A study of Mus musculus with 28 samples.

How the data were processed

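The values are the log2 signals per probe set deposited by the authors, who per their processing notes made them with RMA (background correction, quantile normalization and summary of the probes), in a version that was not given. All 28 arrays were in the table of 22690 probe sets, each array's values matched 1 sample label, and no arrays were identical. No array image or probe intensity was read again. The value ranges and the shape of each array were checked against a log2 scale before any comparison. The third unstimulated day 2 arrays had lower medians than all others, so that one common quantile normalization does not describe the deposited values, and they were used as deposited.

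Probe sets were given gene symbols from the platform annotation, which were matched to the mouse reference genes through the Entrez gene number (20351 matched). Left out were 64 control probe sets, 691 with several symbols and 1555 with none, which leaves 20380 probe sets with 1 symbol. A gene with more than 1 probe set (4956 of 12393 genes) was represented by the probe set with the highest mean over all arrays. Cd69 was not used here, and 1 gene of the naming rule is not reported here. Control probe sets served only for the 3' minus 5' differences and the spike controls. No genome sequence was used.

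Each day was fitted on its own with limma 3.58.1 in R 4.3.3, with a mean per group and moderated variances. The day 2 fit had 12 arrays and 8 residual degrees of freedom before moderation, and the day 5 fit 16 arrays and 10. Comparisons are contrasts of group means, and a difference between cell types is the contrast of both contrasts. Tests were two-sided, p values were adjusted over the 12393 genes by Benjamini and Hochberg, and a gene was called at an adjusted p below 0.05. A leave-one-out fit that leaves a group with 1 array assumes that this array varies like the other groups.

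The comparisons, gene lists, naming rule and alternatives were chosen before the data were examined, except those named as chosen afterwards. The 16 functional lists were T cell activation, quiescence and lymphoid homing, cell cycle, ribosome biogenesis, glycolysis, amino acid transport and one-carbon metabolism, sterol synthesis, oxidative phosphorylation, cytotoxic effectors, cytokines and chemokines, inhibitory receptors, anergy, interferon response, unfolded protein response, BCL2 family, and chemokine receptors and integrins. The 8 marker lists were CD4 helper cells, CD8 cells, pan T cell, regulatory T cell, B cell, myeloid cell, NK cell and red cell. Lists were written from general knowledge of T cells and share some genes. They were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Few calls held with the estimated correlation. The text describes some of the lists of each comparison. Counts given as over the list alone use p values adjusted over its members.

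The naming rule took the 6 largest rises and 6 largest falls among called genes whose groups did not overlap (for differences between cell types, without the overlap rule), up to 3 called members per functional list with the largest change, and a fixed set of marker genes with or without a call. For 3 against 3 arrays, chance gives non-overlapping groups in 10% of genes. The text names about 20 to 30 of these per comparison, picked for their function after the values were seen. Genes whose probe sets had opposite calls were passed over, as were some whose call rested on 1 array.

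Replicate numbers were checked as pairs by correlating, across genes, the deviations from the group means of arrays that share a number, and were taken to pair the arrays where 3 pairs were all above 0.1. This held only for transient against unstimulated CD8 cells on day 5 (r = 0.50, 0.36 and 0.15), where a replicate block gave 3870 called genes beside 3937 without it. The pairing there is a hint from the data, since the labels do not say what the numbers share.

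A self-test added known changes to simulated data with the variances of these arrays, with 100 of 12393 genes changed by 1 and 100 by 3 log2 units. Of the changes of 3, 81% and 77% were called in the day 2 comparisons of CD4 and CD8 cells, and 99% to 100% in those of day 5. Of the changes of 1, 1% was called on day 2 in each cell type and 77% to 91% on day 5. False calls numbered 3 to 15 per comparison.

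The alternatives tried were all probe sets, the mean of probe sets, leaving out the lowest 30% of genes by mean, trend and robust moderation, all 28 arrays in one fit, another quantile normalization, median centring, array weights, a replicate block, only the groups compared, an adjusted p below 0.01, a change of at least 2-fold, an estimated list correlation and leaving out each array in turn. Added after the data were seen were the third unstimulated day 2 arrays left out, the beta-actin measure or the myeloid marker mean as a covariate, and a crossed replicate pairing.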

Results

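Gene expression was measured in 28 preparations of sorted mouse T cells, each on one Affymetrix Mouse 430A2 array, as log2 signal per probe set. The CD4 cells carried the AND receptor transgene (peptide on MHC class II) and the CD8 cells OT1 (class I). CD8 minus CD4 differences cannot part lineage from receptor or antigen. On day 2 there were 12 arrays, 3 each of CD4 and CD8 cells kept in culture without antibody or on plates coated with antibodies to CD3 and CD28, which engage the receptor and its costimulator. All cultures held interleukin 7 at 5 ng per ml, the ligand of the receptor that Il7r encodes. On day 5 there were 16 arrays of cells recovered from host mice. Cells kept unstimulated in culture and then rested in hosts without antigen are called unstimulated, cells stimulated in culture and rested in the same kind of host are called transient, and stimulated cells moved into hosts that present their antigen are called continuous. Each day 5 group had 3 arrays, except CD4 unstimulated and CD4 transient with 2 each. The series text calls the replicates independent biological replicates. The median standard error of a log2 difference was 0.557 for the day 2 comparisons within a cell type, and it lay between 0.148 and 0.182 for those on day 5. Values below are log2 fold changes with their standard error (SE), or group means ± SD in log2 units, and 12393 genes were tested.

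Cd8a parted CD4 from CD8 arrays in every group but one pair. Cd4, the coreceptor of helper cells, stood at 8.77 and 8.41 on the first and second unstimulated CD4 arrays of day 2, and Cd8a, the coreceptor of cytotoxic cells, at 6.59 and 6.90. On the first and second unstimulated CD8 arrays Cd4 stood at 7.35 and 7.21, Cd8a at 11.93 and 11.65, and Zbtb7b, the factor that fixes the helper fate, at 7.59 and 7.10. The third array labelled as unstimulated CD4 cells on day 2 had Cd4 at 5.40, Cd8a at 9.88, Cd8b1 at 10.5 and Zbtb7b at 5.23. The third array labelled as unstimulated CD8 cells on day 2 had Cd4 at 7.02, Cd8a at 5.78, Cd8b1 at 4.79 and Zbtb7b at 6.88, so that Cd8a and Cd8b1 go against its label while Cd4 and Zbtb7b lie below the other CD8 arrays. The median of all probe sets was 4.83 and 4.97 on these 2 arrays, beside 6.29 to 6.53 on the other day 2 arrays. After quantile normalization of the 6 unstimulated arrays, done after the data were seen, Cd4 on this CD8-labelled array was 8.45, beside 6.74 and 6.62 on the other CD8 and 8.62 and 7.82 on the first and second CD4 arrays. Zbtb7b was 8.30, beside 6.95 and 6.53 on the CD8 and 7.99 and 8.57 on the CD4 arrays. All groups were kept as labelled, and the effect of leaving out these 2 arrays is given with each day 2 comparison.

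**Figure D1:**
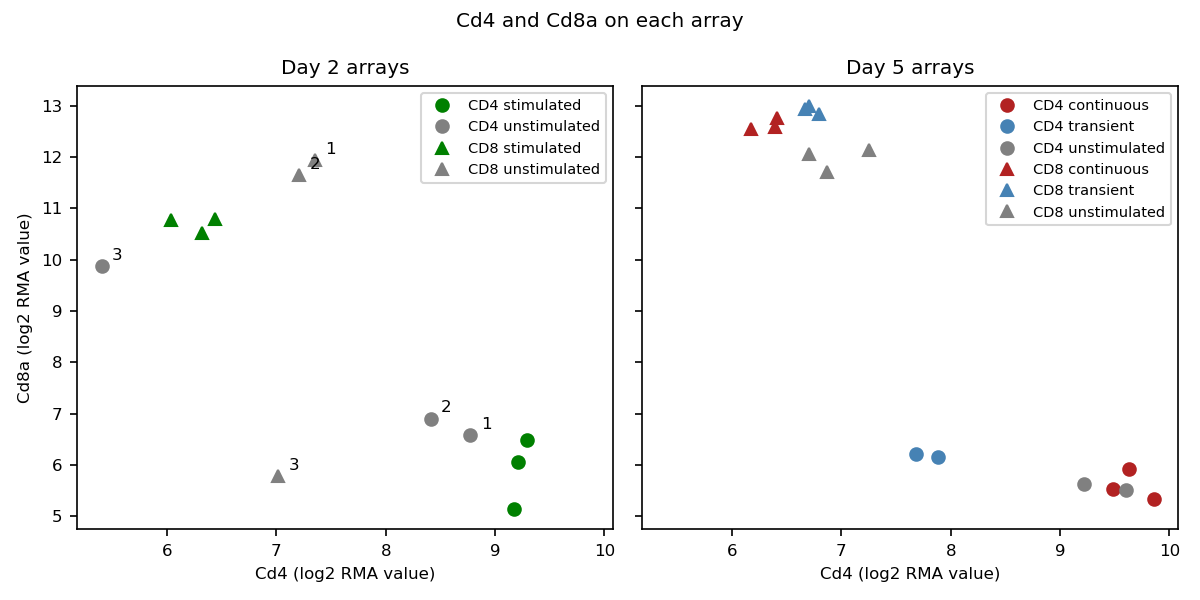
Log2 signal of Cd4 against Cd8a for each of the 28 arrays, with the replicate number beside each unstimulated day 2 array. The third arrays of the unstimulated day 2 groups have Cd8a on the side of the other cell type, at Cd4 5.40 and Cd8a 9.88 for the CD4 label and at Cd4 7.02 and Cd8a 5.78 for the CD8 label.

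The 3' minus 5' signal difference of the beta-actin control probe sets, a sign of shortened RNA or amplification product, differed between groups. On day 2 it ranged from 2.28 to 4.30 on unstimulated arrays and from 1.11 to 1.69 on stimulated arrays. On day 5 it ranged from 2.42 to 2.73 in CD4 transient cells, from 1.92 to 2.44 in CD8 unstimulated cells and from 0.312 to 1.02 in the other groups. It moved with every comparison except CD4 continuous against unstimulated and CD8 continuous against transient.

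**Figure D2:**
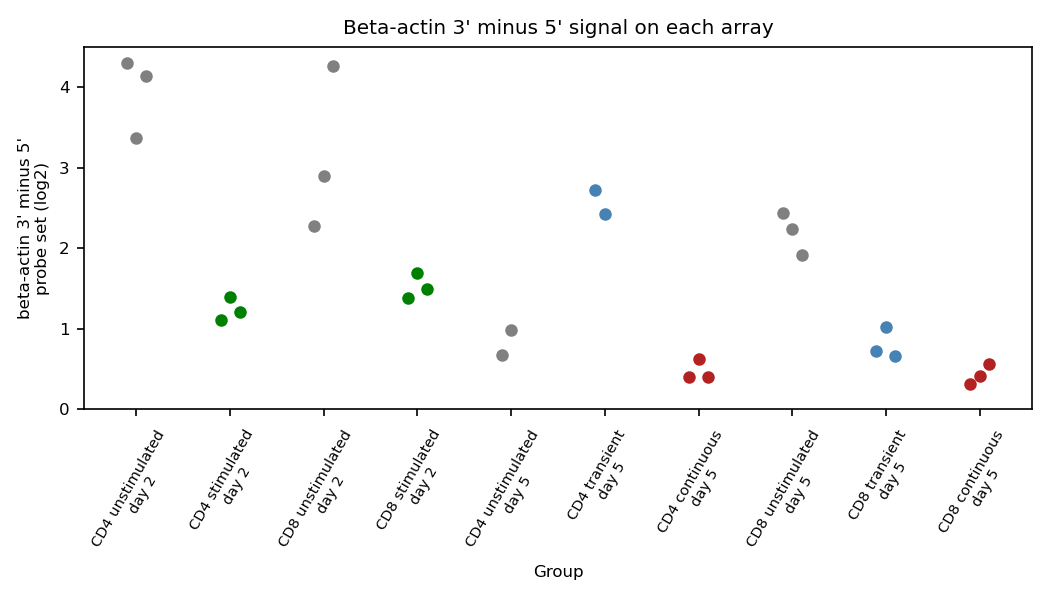
Beta-actin 3' minus 5' difference in log2 units for each array by group. CD4 transient arrays of day 5 lie between 2.42 and 2.73 and CD8 unstimulated arrays between 1.92 and 2.44, while the remaining day 5 arrays lie between 0.312 and 1.02.

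CD4 cells stimulated for 2 days were set against unstimulated CD4 cells, 3 arrays each, to see which genes answer to the receptor and CD28. Cth, which makes cysteine, went from 4.17 ± 1.11 to 12.26 ± 0.58 (8.09, SE 0.54, adjusted p = 5.70e-06), and Asns, which makes asparagine, rose by 7.60 (SE 0.64). Irf4, a transcription factor induced by receptor signals, rose by 7.99 (SE 0.62, adjusted p = 1.86e-05), and Egr2, another early response factor, by 6.38 (SE 0.65). Cdc6, which licenses replication origins, rose by 6.74 (SE 0.68) and Uhrf1, which maintains DNA methylation, by 6.67 (SE 0.72). Il2ra, the high-affinity chain of the interleukin 2 receptor, rose by 5.15 (SE 0.73, adjusted p = 0.000751), and Il2 itself rose by 6.08 (SE 1.02).

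Klf2, a factor that holds T cells at rest, fell (-4.38, SE 0.51, adjusted p = 0.000210), and its target S1pr1, which lets cells leave lymph nodes, fell (-2.97, SE 0.53). The chemokine receptor gene Cxcr4 fell (-4.73, SE 0.79), the receptor chain gene Klrd1 (-5.30, SE 0.96) and the kinase gene Tec (-4.36, SE 0.53). Among inhibitory receptors Ctla4 rose by 4.38 (SE 0.51) and Pdcd1 by 3.80 (SE 0.72, adjusted p = 0.00476), and the receptor ligand gene Cd200 rose by 5.75 (SE 0.68). Tbx21, the master factor of type 1 helper cells, rose by 5.69 (SE 0.55, adjusted p = 5.26e-05), Nr4a1, a reporter of receptor signals, by 5.27 (SE 0.63), and Hk2, the first enzyme of glycolysis, by 5.01 (SE 0.64). Gzmb, a granule protease, rose by 3.86 (SE 0.96, adjusted p = 0.0199). Eomes, a T-box factor of memory cells, showed no call at -0.71 (adjusted p = 0.636), nor did Cd4 at 1.70 (adjusted p = 0.131), and both gained one without the third unstimulated arrays of both cell types (adjusted p = 0.0489 and 0.0130). Cd69 was not analysed here.

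In CD4 cells on day 2, 1320 genes rose and 89 fell, so 93.7% of the called genes rose. The median of all genes was 0.14. Quantile normalization moved that median to -0.15 and the calls to 1438 up and 1484 down. Median centring moved it to -0.48 and the calls to 2173 up and 3727 down, so the share of rising genes rests on the scaling. The cell cycle list had 28 of 32 measured genes up (31 over the list alone), with a median of 3.93 (adjusted p = 3.74e-27, and 0.449 with estimated correlation). The activation list had 13 of 17 up (14 over the list alone, median 3.94, adjusted p = 4.90e-11, and 0.571 with estimated correlation). Amino acid transport and one-carbon metabolism had 10 of 13 up (11 over the list alone, median 3.93, adjusted p = 9.77e-10, and 0.571 with estimated correlation). Ribosome biogenesis had 9 of 19 up (16 over the list alone, median 2.01, adjusted p = 7.35e-07, and 0.689 with estimated correlation). Glycolysis had 6 of 13 up (11 over the list alone, median 2.49, adjusted p = 2.95e-06, and 0.689 with estimated correlation). The unfolded protein response had 9 of 15 (12 over the list alone, median 2.25, adjusted p = 3.59e-06, and 0.689 with estimated correlation). The quiescence list tested down (adjusted p = 0.0160, and 0.698 with estimated correlation) with a negative mean and 3 genes down, although its median was 0.14. Sterol synthesis, oxidative phosphorylation, cytokines and inhibitory receptors tested up at adjusted p = 0.0160, 0.0217, 0.0160 and 0.0400, and at 0.698, 0.776, 0.698 and 0.731 with estimated correlation. The regulatory T cell markers tested up with 2 of 6 genes called (4 over the list alone, median 1.60, adjusted p = 0.0167, and 0.698 with estimated correlation). The myeloid markers tested down with 0 called (0 over the list alone, median -0.33, adjusted p = 0.0263, and 0.717 with estimated correlation).

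In these CD4 cells leaving out the third array with the unstimulated CD4 label raised the count of called genes from 1409 to 3289, of which 1039 rose and 2250 fell. Leaving out any one stimulated CD4 array lowered it, to 566 without the first, 688 without the second and 614 without the third. Without the third unstimulated arrays of both cell types 8139 genes were called, 3251 up and 4888 down, all 1320 rises and 89 falls above were kept with 0 opposite calls, and the median of all genes was -0.31. Without these 2 arrays the lists of quiescence (adjusted p = 0.419), cytokines (adjusted p = 0.219), inhibitory receptors (adjusted p = 0.314) and regulatory T cell markers (adjusted p = 0.172) lost their call. Median centring ended that of quiescence (adjusted p = 0.0740) and inhibitory receptors (adjusted p = 0.0556). Leaving out low values ended that of sterol synthesis (adjusted p = 0.0936), oxidative phosphorylation (adjusted p = 0.233) and inhibitory receptors (adjusted p = 0.0745). The call of Gzmb was lost with array weights (adjusted p = 0.17) and without the third unstimulated (adjusted p = 0.06), the first stimulated (adjusted p = 0.089) or the second stimulated array (adjusted p = 0.093), and its adjusted p ranged from 0.00185 to 0.168 over all alternatives. The beta-actin measure moved with these genes.

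CD8 cells stimulated for 2 days were set against unstimulated CD8 cells, 3 arrays each, with the same question. Gzmb rose from 5.64 ± 0.67 to 13.16 ± 0.19 (7.53, SE 0.96, adjusted p = 0.000364), and Ifng, the main type 1 cytokine, rose by 5.99 (SE 0.99, adjusted p = 0.00241). Cth rose by 8.34 (SE 0.54) and Asns by 7.17 (SE 0.64), as in CD4 cells. Cdca5, which holds sister chromatids together, rose by 7.05 (SE 0.80), Rrm2, which makes DNA building blocks, by 6.74 (SE 0.59), Cdc6 by 6.82 (SE 0.68) and the proliferation marker Mki67 by 5.55 (SE 0.72, adjusted p = 0.000409). The osteoclast factor gene Tnfsf11 rose by 6.84 (SE 0.69) and the myeloid growth factor gene Csf2 by 5.71 (SE 0.71).

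Il2ra rose by 5.29 (SE 0.73, adjusted p = 0.000637), Irf4 by 6.34 (SE 0.62), Tbx21 by 4.46 (SE 0.55), the scramblase gene Plscr1 by 7.11 (SE 0.61) and the surface marker gene Cd83 by 6.86 (SE 0.85). Ctla4 rose by 5.10 (SE 0.51, adjusted p = 5.81e-05), Pdcd1 by 3.81 (SE 0.72) and Cd200 by 5.53 (SE 0.68). Hk2 rose by 4.62 (SE 0.64) and the death gene Pmaip1 by 3.26 (SE 0.45). Klf2 fell (-5.62, SE 0.51, adjusted p = 3.21e-05), Hcst, the adaptor of a killer cell receptor, (-5.09, SE 0.42) and the actinin gene Actn2 (-4.50, SE 0.73). Lag3 and Eomes showed no call, at 1.21 (adjusted p = 0.201) and 0.16 (adjusted p = 0.954), and gained one with array weights (adjusted p = 0.00589 and 0.00244) and without the third unstimulated arrays of both cell types (adjusted p = 0.0284 and 0.0108).

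In CD8 cells on day 2, 928 genes rose and 107 fell, so 89.7% of the called genes rose, with a median of all genes of 0.14. Quantile normalization gave 1309 up and 1300 down with a median of -0.15, and median centring 1892 up and 3091 down with a median of -0.48. The cell cycle list had 29 of 32 genes up (31 over the list alone, median 4.35, adjusted p = 2.19e-33, and 0.275 with estimated correlation). The activation list had 13 of 17 (16 over the list alone, median 3.97, adjusted p = 7.14e-13, and 0.620 with estimated correlation). Amino acid transport and one-carbon metabolism had 9 of 13 up (11 over the list alone, median 3.50, adjusted p = 1.50e-08, and 0.620 with estimated correlation). The regulatory T cell marker list, which holds Il2ra and Ctla4, had 3 of 6 up (3 over the list alone, median 1.91, adjusted p = 0.0440, and 0.690 with estimated correlation). The interferon response list had 0 up and 0 down (0 and 0 over the list alone), a median of 0.25 and a test direction of down (adjusted p = 0.514).

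In these CD8 cells leaving out the second unstimulated array raised the count of called genes from 1035 to 1692, and leaving out the first, the second or the third stimulated array lowered it to 438, 387 or 420. Without the third unstimulated arrays of both cell types 4691 genes were called, 2040 up and 2651 down, with 923 of the 928 rises and all 107 falls kept, 0 opposite calls and a median of all genes of -0.22. The list of regulatory T cell markers lost its call without these 2 arrays (adjusted p = 0.185) and with median centring (adjusted p = 0.0665). The responses of CD4 and CD8 cells correlated across genes at r = 0.92, with 774 genes up in both where 98.8 were expected by chance, though genes are not independent replicates. The beta-actin measure moved with these genes as well.

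The CD8 minus CD4 difference of the stimulation response asked which genes answer differently in both lineages, and limma called 0 genes, with 70 at an unadjusted p below 0.05. Gzmb differed by 3.66 (SE 1.36) and Ifng by 2.11 (SE 1.40), Tbx21 by -1.23 (SE 0.77) and Il2ra by 0.15 (SE 1.03), all at an adjusted p of 1.00. Cd4 and Cd8a differed by -2.62 (SE 0.96) and 2.80 (SE 1.84), and the levels of both genes on the third unstimulated arrays enter these values. The cytotoxic list was higher in the CD8 response with 0 called members (2 over the list alone, median 0.59, adjusted p = 2.54e-08, and 0.537 with estimated correlation). Glycolysis was lower in CD8 cells with 0 called members (0 over the list alone, median -0.56, adjusted p = 0.000894, and 0.985 with estimated correlation). The marker lists of CD4 helper cells (median -0.48, adjusted p = 0.00408, and 0.537 with estimated correlation) and CD8 cells (median 2.49, adjusted p = 0.0105, and 0.537 with estimated correlation) moved in opposite directions.

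Leaving out the second or the third unstimulated CD4 array gave 1 or 2 called genes for this difference. Without the third unstimulated arrays of both cell types 308 genes were called, 89 higher and 219 lower in the CD8 response. Klrc1, an inhibitory receptor chain of killer cells, then differed by 3.97 (SE 0.57, adjusted p = 0.0187) and the chemokine gene Xcl1 by 3.66 (SE 0.73, adjusted p = 0.0427). Ccr9, a gut homing receptor, differed by -4.29 (SE 0.75, adjusted p = 0.0326), the granule gene Nkg7 by -3.79 (SE 0.53, adjusted p = 0.0175) and the chemokine gene Ccl5 by -3.62 (SE 0.56, adjusted p = 0.0249). Among the lists, the cytotoxic one (median 0.76, adjusted p = 0.0523) and the CD4 helper markers (median -0.25, adjusted p = 0.261) lost their call without these 2 arrays, and the CD8 markers turned to a median of -0.95 (adjusted p = 0.232). The CD8 markers also lost their call with median centring (adjusted p = 0.0852). Ribosome biogenesis (median -0.84, adjusted p = 0.000289), oxidative phosphorylation (median -0.59, adjusted p = 0.00117), the unfolded protein response (median -0.98, adjusted p = 0.00296) and quiescence (median -0.41, adjusted p = 0.0436) gained one, each lower in the CD8 response. This alternative was chosen after the lineage genes had been seen.

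Transient CD4 cells on day 5 were set against unstimulated CD4 cells, 2 arrays each, to ask what remains of the stimulation after 3 days without antigen. Cxcr3, which guides cells to inflamed tissue, stood at 12.85 ± 0.20 against 7.90 ± 0.16 (4.95, SE 0.32, adjusted p = 1.20e-06). Ctla4 was higher by 3.45 (SE 0.38, adjusted p = 4.41e-05), Cd44, a memory marker, by 3.60 (SE 0.51), Il2ra by 2.90 (SE 0.48) and Tbx21 by 2.27 (SE 0.43, adjusted p = 0.00216). Nkg7 was higher by 2.43 (SE 0.17), Hk2 by 2.88 (SE 0.59), Rrm2 by 3.30 (SE 0.60) and Pmaip1 by 2.90 (SE 0.54). Lef1, a factor of naive cells, was lower (-2.53, SE 0.37), S1pr1 (-2.51, SE 0.28) and Klf2 (-1.84, SE 0.22). The quiescence list that holds them did not pass (4 of 15 down, 4 over the list alone, median -0.56, adjusted p = 0.0685).

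B cell genes were among the largest rises in the same transient CD4 arrays. Ms4a1, which encodes CD20, stood at 11.99 ± 1.22 against 6.32 ± 1.44 (5.67, SE 1.38, adjusted p = 0.00930), Cd79b of the B cell receptor was higher by 5.01 (SE 0.64) and the lymphoid marker gene Ly6d by 5.80 (SE 1.15). The call of Ms4a1 was lost without the second unstimulated array (adjusted p = 0.089) or the first transient array (adjusted p = 0.076), with a range of 0.00287 to 0.924 over all alternatives. The B cell marker list had 4 of 12 genes up (9 over the list alone, median 2.61, adjusted p = 0.00107, and 0.684 with estimated correlation). The proteasome genes Psmb7 (-3.97, SE 0.21, adjusted p = 3.00e-07) and Psmc5 (-3.30, SE 0.28) were lower, as were the phosphatase gene Phpt1 (-3.25, SE 0.21), the adaptor gene Pdlim4 (-3.99, SE 0.29) and the receptor partner gene Ramp1 (-3.35, SE 0.67). Tnfrsf9, a costimulatory receptor, was lower (-2.45, SE 0.28), Eomes (-2.11, SE 0.35, adjusted p = 0.000757) and Cd4 (-1.63, SE 0.19). Gzmb (1.74, adjusted p = 0.164), Ifng (1.57, adjusted p = 0.160) and Il7r (-1.41, adjusted p = 0.270) had no call and gained one in a fit of the 4 compared arrays alone, at adjusted p = 0.019, 0.020 and 0.020. Over all alternatives their adjusted p ranged from 0.0188 to 0.874, 0.0205 to 0.944 and 0.0203 to 0.949. Pdcd1 differed by -0.35 (adjusted p = 0.679).

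In transient CD4 cells 1197 genes were higher and 1624 lower. The cell cycle list was up with 6 genes up and 2 down (14 and 3 over the list alone, median 0.91, adjusted p = 0.0188, and 0.848 with estimated correlation). Ribosome biogenesis was down with 1 up and 5 down (1 and 5 over the list alone, median -0.41, adjusted p = 0.0233, and 0.817 with estimated correlation). The helper lineage markers were lower (2 of 3, 2 over the list alone, median -1.47, adjusted p = 0.0133, and 0.684 with estimated correlation). Activation (4 up and 1 down, 5 and 1 over the list alone, median 0.28, adjusted p = 0.165) and anergy (0 up and 0 down, 0 and 0 over the list alone, median -0.10, adjusted p = 0.680) did not pass. Interferon response genes did not pass either, with a median of 0.23 and a negative mean and test (adjusted p = 0.920).

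These CD4 differences moved with the beta-actin measure, which ran from 2.42 to 2.73 in the transient cells. The count of 2821 fell to 1671 or 1748 without the first or second unstimulated array, to 87 in a fit of all 28 arrays and to 4 with the beta-actin measure as a covariate, an alternative chosen after the data were seen. With that covariate the lists of B cell (adjusted p = 0.329) and helper lineage markers (adjusted p = 0.252) lost their call, and the interferon response list turned up and gained one (median 1.28, adjusted p = 0.0448). Ribosome biogenesis lost its call with low values left out (adjusted p = 0.108).

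Transient CD8 cells on day 5 were set against unstimulated CD8 cells, 3 arrays each, with the same question. Ctla4 stood at 10.58 ± 0.24 against 6.65 ± 0.12 (3.94, SE 0.31, adjusted p = 1.44e-06) and Tbx21 was higher by 3.02 (SE 0.35, adjusted p = 3.05e-05). The inhibitory receptor chain gene Klrc1 was higher by 3.45 (SE 0.32) and the activating receptor gene Klrk1 by 2.91 (SE 0.17). Ccr9 fell from 10.30 ± 0.42 to 4.44 ± 0.06 (-5.87, SE 0.40, adjusted p = 5.10e-07). Cd200 was higher by 2.69 (SE 0.27), Itgb1, an integrin of memory cells, by 1.93 (SE 0.29), Cxcr3 by 1.91 (SE 0.26) and Ccl5 by 1.69 (SE 0.39).

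Batf, a factor of effector cells, was higher by 1.69 (SE 0.18), the costimulator gene Icos by 1.48 (SE 0.26) and Lag3 by 1.30 (SE 0.29, adjusted p = 0.00350). Plscr1 was higher by 4.63 (SE 0.29, adjusted p = 2.62e-07), the calcium binding protein gene S100a6 by 3.18 (SE 0.53), the protease inhibitor gene Ctla2b by 3.22 (SE 0.41), Ldha of glycolysis by 1.10 (SE 0.10) and Psmb7 by 3.91 (SE 0.17). Eomes was lower (-2.17, SE 0.28, adjusted p = 7.19e-05), the checkpoint kinase gene Chek1 (-2.61, SE 0.45), the Wnt pathway gene Cxxc5 (-2.96, SE 0.39), the cell cycle regulator gene Rgcc (-2.70, SE 0.35) and the receptor gene Adgrg3 (-3.18, SE 0.36). Cd8a was higher by 0.95 (SE 0.15). Ifng (0.57, adjusted p = 0.518) and Il7r (0.11, adjusted p = 0.924) had no call. Mki67 had none either (1.32, adjusted p = 0.0572) but gained one with replicate numbers as a block (adjusted p = 0.027) and without the first unstimulated array (adjusted p = 0.00277), in a range of 0.00277 to 0.881 over all alternatives.

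In transient CD8 cells 2020 genes were higher and 1917 lower. Oxidative phosphorylation genes were up with 12 higher and 2 lower of 26 (13 and 2 over the list alone, median 0.28, adjusted p = 0.00848, and 0.301 with estimated correlation). The pan T cell markers were up (4 of 7, 5 over the list alone, median 0.58, adjusted p = 0.00930, and 0.301 with estimated correlation). The cytotoxic list did not pass (5 up, 5 over the list alone, median 0.17, adjusted p = 0.0818), nor did the cytokine list (3 up, 2 over the list alone), whose median of -0.11 was negative while its test pointed up (adjusted p = 0.951). The inhibitory receptor list had a median of -0.11 and a positive mean and test (adjusted p = 0.753). Red cell markers had 1 gene down (1 over the list alone, median -0.53, adjusted p = 0.626).

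The beta-actin measure moved with these CD8 differences in the opposite sense, since it was high in the unstimulated cells. The count of 3937 fell to 239 in a fit of all 28 arrays and to 156 with the beta-actin measure as a covariate. Oxidative phosphorylation lost its call with that covariate (adjusted p = 0.530) and with low values left out (adjusted p = 0.0884), as did the pan T cell markers with low values left out (adjusted p = 0.0884).

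The transient responses of CD4 and CD8 cells were compared as a difference, CD8 minus CD4, to ask whether both lineages keep the same trace of stimulation. Ctla4 and Tbx21, higher in both, had no call (0.49, adjusted p = 0.466, and 0.75, adjusted p = 0.315), and Eomes, lower in both, had none (-0.05, adjusted p = 0.939). S1pr1, Lef1 and Klf2 were lower in transient CD4 cells and higher in transient CD8 cells, by 1.36 (SE 0.23, adjusted p = 0.000573), 1.27 (SE 0.30, adjusted p = 0.00567) and 1.15 (SE 0.18, adjusted p = 0.000332). The CD8 calls of all 3 were lost in a fit of all 28 arrays and with the beta-actin measure as a covariate, which turned the sign of S1pr1 (-0.207) and Lef1 (-0.183) there. Between the responses S1pr1 differed by 3.87 (SE 0.37, adjusted p = 3.17e-06), Lef1 by 3.80 (SE 0.48) and Klf2 by 2.99 (SE 0.29). Ccr9 differed by -6.31 (SE 0.64), Klrk1 by 3.28 (SE 0.27), Klrc1 by 3.17 (SE 0.50), Cd200 by 3.27 (SE 0.43), Il2ra by -2.52 (SE 0.62) and Cxcr3 by -3.04 (SE 0.41). Pkm of glycolysis differed by 3.65 (SE 0.43).

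Between the transient responses Psmb7 differed by 7.88 (SE 0.27, adjusted p = 1.48e-09), Psmc5 by 6.10 (SE 0.36), Phpt1 by 5.93 (SE 0.27), the lysosome gene Plekhj1 by 5.59 (SE 0.35), the transcription factor gene Nfx1 by 5.57 (SE 0.24) and the splicing gene Cwc15 by 5.41 (SE 0.26). Ms4a1 differed by -7.02 (SE 1.78), and Scd1, which desaturates fatty acids, by -5.90 (SE 0.88). The B cell marker list was lower in the CD8 response (5 of 12, 5 over the list alone, median -2.74, adjusted p = 0.0361, and 0.900 with estimated correlation). The pan T cell list was higher (4 of 7, 4 over the list alone, median 1.21, adjusted p = 0.0153, and 0.705 with estimated correlation). Oxidative phosphorylation was higher (12 up and 3 down, 12 and 5 over the list alone, median 0.44, adjusted p = 0.0153, and 0.705 with estimated correlation).

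In all, 2298 genes were higher and 2344 lower in the CD8 than in the CD4 transient response, with a median of all genes of -0.14 that became -0.01 with quantile normalization. The responses correlated across genes at r = -0.52, with 604 genes up in CD4 and down in CD8 cells where 185 were expected by chance, 1111 the other way where 265 were expected, 64 up in both and 45 down in both. The beta-actin measure moved in opposite senses in both responses, 525 genes were called in a fit of all 28 arrays and 11 with it as a covariate. Its use as a covariate turned the sign for Cd4, from 1.41 (SE 0.24) to -0.29. It ended the list calls of B cell markers (adjusted p = 0.948) and oxidative phosphorylation (adjusted p = 0.698). With low values left out the B cell and pan T cell markers (adjusted p = 0.109 for both) and oxidative phosphorylation (adjusted p = 0.115) lost theirs. The B cell markers also lost it with the myeloid markers as a covariate (adjusted p = 0.0710), an alternative chosen after the data were seen.

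Continuous CD4 cells, 3 arrays, were set against transient CD4 cells, 2 arrays, to ask what antigen in the host maintains. Il21, a cytokine of follicular helper cells, stood at 10.51 ± 0.51 against 4.25 ± 0.84 (6.26, SE 0.30, adjusted p = 5.25e-08), and Gzmb at 12.76 ± 0.48 against 7.05 ± 0.37 (5.71, SE 0.77, adjusted p = 7.87e-05). Gzmk, another granule protease, was higher by 4.78 (SE 0.52, adjusted p = 1.45e-05), Ifng by 4.25 (SE 0.69, adjusted p = 0.000316), the chemokine gene Ccl4 by 3.12 (SE 0.67) and the regulatory cytokine gene Il10 by 3.07 (SE 0.37). The mitosis gene Ccna2 was higher by 4.50 (SE 0.56), Aurka by 4.24 (SE 0.47), Plk1 by 4.17 (SE 0.49) and Mki67 by 2.95 (SE 0.55, adjusted p = 0.000961). Tbx21 was higher by 2.90 (SE 0.40), Icos by 1.82 (SE 0.29), Tnfrsf9 by 1.68 (SE 0.26), Lag3 by 2.12 (SE 0.32) and Cd200 by 2.37 (SE 0.31).

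In these continuous CD4 cells Pkm of glycolysis was higher by 3.39 (SE 0.30), Ldha by 1.81 (SE 0.11) and Cyp51 of sterol synthesis by 2.80 (SE 0.26). Ccr7, which keeps cells in lymph nodes, was lower (-1.75, SE 0.33) and the survival gene Bcl2 (-1.28, SE 0.26). Il7r was lower (-2.71, SE 0.78, adjusted p = 0.0148), a call lost without the first transient array (adjusted p = 0.052) or the second (adjusted p = 0.088) and in a fit of the compared arrays alone (adjusted p = 0.109). Its adjusted p ranged from 0.00387 to 0.950 over all alternatives, and its sign turned with the beta-actin measure as a covariate (0.99). Psmb7 was higher by 4.95 (SE 0.19) and Cd4 by 1.88 (SE 0.17). The B cell genes Ms4a1 (-6.89, SE 1.26), Ly6d (-6.24, SE 1.05) and Cd79b (-5.71, SE 0.58) were lower, and their list had 9 of 12 down (12 over the list alone, median -2.74, adjusted p = 0.000350, and 0.346 with estimated correlation). Ctla4 (0.62, adjusted p = 0.194) and Eomes (0.63, adjusted p = 0.144) had no call.

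In continuous against transient CD4 cells 2182 genes were higher and 2042 lower. All 32 cell cycle genes were up (32, and 32 over the list alone, median 2.43, adjusted p = 5.81e-17, and 0.215 with estimated correlation). Sterol synthesis had 10 of 14 up (10 over the list alone, median 1.11, adjusted p = 0.000352, and 0.215 with estimated correlation). Glycolysis had 9 up and 2 down (9 and 2 over the list alone, median 1.42, adjusted p = 0.00154, and 0.215 with estimated correlation). The cytotoxic list had 10 of 19 up (11 over the list alone, median 0.91, adjusted p = 0.000350, and 0.215 with estimated correlation). Inhibitory receptors had 5 of 16 (5 over the list alone, median 0.70, adjusted p = 0.0118, and 0.0975 with estimated correlation). The BCL2 family list had 2 up and 4 down (2 and 4 over the list alone, median -0.08, adjusted p = 0.659). The beta-actin measure moved with these differences, and the count of 4224 became 618 in a fit of all 28 arrays and 2 with that measure as a covariate. The lists of glycolysis (adjusted p = 0.351), cytotoxic genes (adjusted p = 0.476) and B cell markers (adjusted p = 0.351) lost their call with it.

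**Figure D3:**
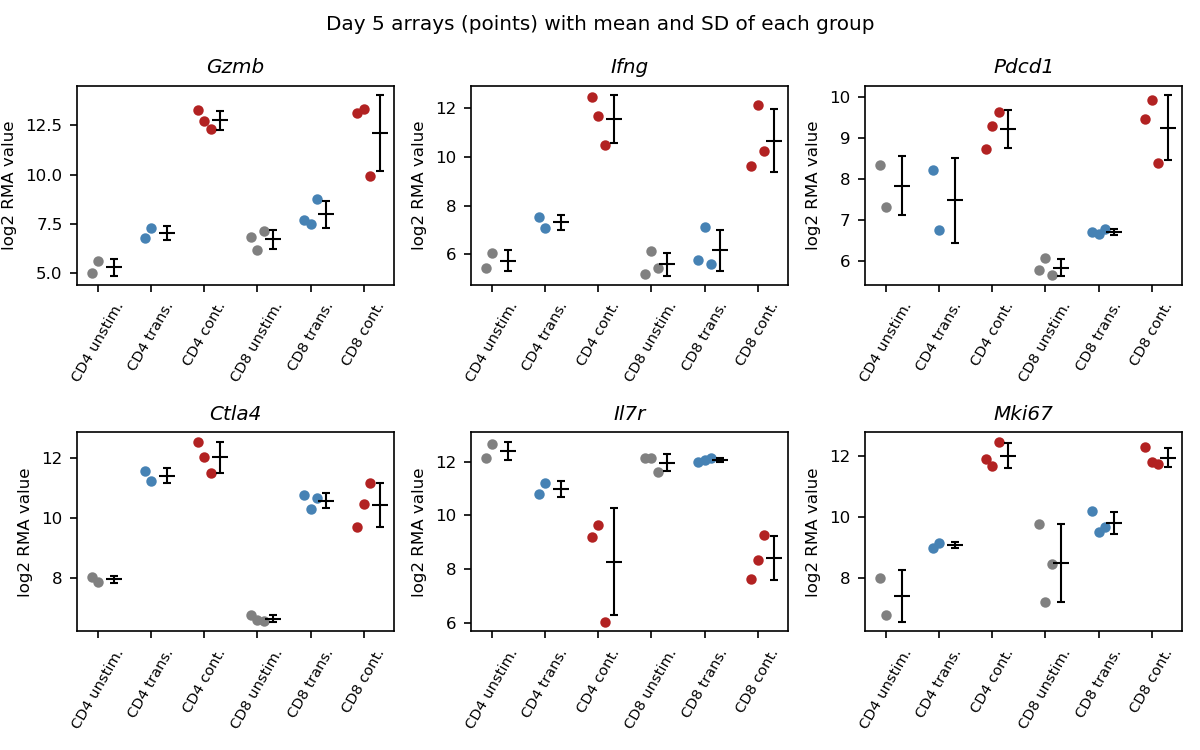
Log2 signal of Gzmb, Ifng, Pdcd1, Ctla4, Il7r and Mki67 on each day 5 array, with the group mean and SD. Gzmb in CD4 cells stands at 5.31 ± 0.44 unstimulated, 7.05 ± 0.37 transient and 12.76 ± 0.48 continuous.

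Continuous CD8 cells were set against transient CD8 cells, 3 arrays each, with the same question; the beta-actin measure did not part these groups. Ifng stood at 10.67 ± 1.30 against 6.16 ± 0.85 (4.52, SE 0.62, adjusted p = 0.000161) and Gzmb at 12.12 ± 1.91 against 7.99 ± 0.67 (4.13, SE 0.69, adjusted p = 0.000630). Gzmk was higher by 4.88 (SE 0.46, adjusted p = 1.88e-05), and the chemokine genes Ccl4 and Xcl1 by 4.03 (SE 0.60) and 3.58 (SE 0.37). The inhibitory receptor gene Havcr2 was higher by 3.63 (SE 0.88, adjusted p = 0.00709) and Pdcd1 by 2.53 (SE 0.41, adjusted p = 0.000558). Il7r, which takes up a survival signal, was lower (-3.66, SE 0.69, adjusted p = 0.00146), as was Il6ra of the interleukin 6 receptor (-3.30, SE 0.33).

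Tnfrsf9 was higher by 3.47 (SE 0.23, adjusted p = 3.03e-06), Nr4a1 by 2.74 (SE 0.46), Irf8 by 2.85 (SE 0.52), Eomes by 2.08 (SE 0.28) and Il2ra by 2.20 (SE 0.39). Cdc6 was higher by 3.78 (SE 0.51) and Mcm5, part of the replicative helicase, by 3.51 (SE 0.30), and Mki67 was higher by 2.15 (SE 0.49, adjusted p = 0.00513). Shmt1 of one-carbon metabolism was higher by 2.78 (SE 0.30), Asns by 2.78 (SE 0.38), Tpi1 of glycolysis by 2.48 (SE 0.30) and Nop58, a ribosome assembly factor, by 1.77 (SE 0.27). Txnip, which limits glucose uptake, was lower (-2.12, SE 0.23), Ccr7 (-1.51, SE 0.29), Itgae, an integrin of tissue cells, (-2.67, SE 0.28), the signalling brake gene Socs3 (-2.13, SE 0.38) and Dtx1, linked to anergy, (-2.02, SE 0.29). Ctla4 had no call (-0.13, adjusted p = 0.820), nor did Tbx21 (0.21, adjusted p = 0.736), which gained one without the third continuous array (0.74, adjusted p = 0.032, in a range of 0.0323 to 1.00 over all alternatives).

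In continuous against transient CD8 cells 1686 genes were higher and 1690 lower. All 32 cell cycle genes were up (32, and 32 over the list alone, median 2.54, adjusted p = 2.71e-24, and 0.140 with estimated correlation). Ribosome biogenesis had 14 of 19 up (15 over the list alone, median 0.92, adjusted p = 5.63e-10, and 0.140 with estimated correlation). Quiescence had 12 of 15 down (13 over the list alone, median -1.23, adjusted p = 1.12e-06, and 0.187 with estimated correlation). Interferon response had 3 of 17 (11 over the list alone, median -1.02, adjusted p = 0.000925, and 0.398 with estimated correlation). Inhibitory receptors had 9 of 16 up (9 over the list alone, median 0.95, adjusted p = 0.000416, and 0.0552 with estimated correlation). The unfolded protein response had 10 up and 1 down (12 and 2 over the list alone, median 0.90, adjusted p = 0.000107, and 0.140 with estimated correlation). Anergy had 1 up and 3 down (1 and 4 over the list alone, median -0.20, adjusted p = 0.172). The pan T cell markers were lower (4 of 7, 4 over the list alone, median -0.41, adjusted p = 0.0169, and 0.259 with estimated correlation), a call lost with the beta-actin measure as a covariate (adjusted p = 0.0629). Marker lists of myeloid cells (median -0.16, adjusted p = 0.992) and NK cells (median -0.03, adjusted p = 0.993) did not pass. The count of 3376 became 360 in a fit of all 28 arrays and 5135 with array weights.

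The effect of antigen in the host was compared between lineages as the CD8 minus CD4 difference of continuous against transient cells. Il21, higher in continuous CD4 cells, differed by -6.13 (SE 0.41, adjusted p = 3.73e-06), as did the growth factor gene Tgfb3 (-4.11, SE 0.29) and Gja1 of gap junctions (-3.73, SE 0.34). In CD8 cells the means of these 3 genes were low (3.08 to 4.64), near the lower end of the signal, so the sizes of their differences are uncertain. Il2ra differed by 3.23 (SE 0.59, adjusted p = 0.00209), Xcl1 by 3.78 (SE 0.56) and the death ligand gene Fasl by 4.05 (SE 0.76), each higher in the CD8 response. Tbx21 differed by -2.68 (SE 0.53), Nkg7 by -3.23 (SE 0.20), the granule protease gene Ctsw by -2.87 (SE 0.28), Ccl5 by -3.41 (SE 0.58) and the phosphatase gene Cdc25b by -3.41 (SE 0.53), each higher in the CD4 response. Gzmb (-1.58, adjusted p = 0.348), Ifng (0.26, adjusted p = 0.895) and Pdcd1 (0.81, adjusted p = 0.441) had no call.

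S1pr1 differed by -2.92 (SE 0.35), Klf2 by -2.23 (SE 0.27), Cxcr6, a receptor of tissue cells, by -2.91 (SE 0.51) and Itgae by -2.28 (SE 0.42). The chemokine receptor and integrin list was lower in CD8 cells (1 up and 6 down, 1 and 6 over the list alone, median -0.79, adjusted p = 0.00286, and 0.0683 with estimated correlation). The ribosome genes Fbl and Gnl3 differed by 1.63 (SE 0.21) and 2.27 (SE 0.46). Their list had 7 up and 1 down (9 and 2 over the list alone, median 0.73, adjusted p = 0.0106, and 0.710 with estimated correlation). Activation genes were higher (5 up and 2 down, 7 and 2 over the list alone, median 0.86, adjusted p = 0.0373, and 0.710 with estimated correlation) in CD8 cells. Quiescence was lower (3 down, 5 over the list alone, median -0.70, adjusted p = 0.0186, and 0.710 with estimated correlation). The B cell genes Cd79b (5.33, SE 0.78) and Ms4a1 (7.13, SE 1.69), high in transient CD4 cells, moved with these differences, and Ms4a1 lost its call without the first transient CD4 array (adjusted p = 0.056, in a range of 0.00154 to 0.819 over all alternatives). In all, 1008 genes were higher and 1332 lower in the CD8 response, 22 were called in a fit of all 28 arrays and 4 with the beta-actin measure as a covariate, and that measure moved with the CD4 part. With the covariate the lists of activation (adjusted p = 0.333), quiescence (adjusted p = 0.106), ribosome biogenesis (adjusted p = 0.333) and chemokine receptors and integrins (adjusted p = 0.174) lost their call. Quiescence also lost it with low values left out (adjusted p = 0.0595).

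Continuous CD4 cells, 3 arrays, were set against unstimulated CD4 cells, 2 arrays, which gives the full change by day 5 in groups with a like beta-actin measure. Gzmb stood at 12.76 ± 0.48 against 5.31 ± 0.44 (7.45, SE 0.77, adjusted p = 2.77e-05), Il21 was higher by 6.44 (SE 0.30, adjusted p = 6.68e-08) and Ifng by 5.83 (SE 0.69, adjusted p = 7.10e-05). Tbx21 was higher by 5.16 (SE 0.40, adjusted p = 2.73e-06) with genes it is known to drive, Cxcr3 at 4.86 (SE 0.29) and Ccl5 at 4.15 (SE 0.43). Nkg7 was higher by 5.69 (SE 0.15), Ccl4 by 3.98 (SE 0.67), Cxcr6 by 3.00 (SE 0.38) and the membrane protein gene Emp1 by 5.65 (SE 0.62). Ctla4 was higher by 4.07 (SE 0.35, adjusted p = 8.08e-06) and Lag3 by 2.31 (SE 0.32).

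The mitosis gene Cdk1 was higher by 5.43 (SE 0.67), Aurkb by 5.43 (SE 0.59), Ube2c by 5.38 (SE 0.66) and Mki67 by 4.62 (SE 0.55). Also higher were Hk2 (2.73, SE 0.54), Tpi1 (2.25, SE 0.34), Asns (2.69, SE 0.43), Irf4 (2.73, SE 0.60) and Pmaip1 (3.94, SE 0.49). Il7r was lower (-4.12, SE 0.78, adjusted p = 0.00197), Bcl2 (-1.65, SE 0.26), Ccr7 (-2.36, SE 0.33), Ramp1 (-4.96, SE 0.61), Pdlim4 (-4.38, SE 0.26) and the transport gene Rab6b (-4.16, SE 0.40). Eomes was lower (-1.48, SE 0.32, adjusted p = 0.00448) and Foxp3 (-1.07, SE 0.25, adjusted p = 0.00846), calls lost without the second unstimulated array (adjusted p = 0.055 and 0.073, in ranges of 0.000759 to 0.438 and 0.00460 to 0.289 over all alternatives). Pdcd1 differed by 1.38 (adjusted p = 0.0503) and gained a call without the first unstimulated (adjusted p = 0.048) or the first continuous array (adjusted p = 0.044), in a range of 0.0157 to 0.610 over all alternatives.

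In continuous against unstimulated CD4 cells 1229 genes were higher and 1341 lower. All 32 cell cycle genes were up (32, and 32 over the list alone, median 3.80, adjusted p = 3.01e-32, and 0.112 with estimated correlation). Quiescence had 10 of 15 down (11 over the list alone, median -1.06, adjusted p = 3.15e-05, and 0.245 with estimated correlation). The cytotoxic list had 8 of 19 up (8 over the list alone, median 0.46, adjusted p = 4.44e-05, and 0.117 with estimated correlation). Cytokines had 4 of 19 up (4 over the list alone, median 0.26, adjusted p = 0.00357, and 0.245 with estimated correlation). Inhibitory receptors had 7 up and 1 down (9 and 1 over the list alone, median 1.10, adjusted p = 0.00122, and 0.0398 with estimated correlation). Chemokine receptors and integrins had 6 of 15 up (6 over the list alone, median 0.81, adjusted p = 0.000555, and 0.0398 with estimated correlation). These last 2 lists kept their call with an estimated correlation, and cytokines lost theirs with low values left out (adjusted p = 0.120). The count of 2570 became 1480 or 1361 without the first or second unstimulated array and 329 in a fit of all 28 arrays.

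Continuous CD8 cells were set against unstimulated CD8 cells, 3 arrays each, and here the beta-actin measure was high in the unstimulated cells and moved with the differences. Gzmb was higher by 5.40 (SE 0.69, adjusted p = 2.85e-05), Ifng by 5.09 (SE 0.62, adjusted p = 1.81e-05) and Gzmk by 4.92 (SE 0.46). Pdcd1 was higher by 3.40 (SE 0.41, adjusted p = 1.88e-05), Ctla4 by 3.80 (SE 0.31), Lag3 by 2.13 (SE 0.29) and Cd200 by 4.68 (SE 0.27). Tbx21 was higher by 3.23 (SE 0.35), Irf4 by 3.18 (SE 0.54), Il2ra by 2.58 (SE 0.39), Tnfrsf9 by 3.55 (SE 0.23) and Xcl1 by 3.84 (SE 0.37). Ccr9 was lower (-5.68, SE 0.40, adjusted p = 2.64e-07), Il7r (-3.55, SE 0.69, adjusted p = 0.000871) and Itgae (-3.28, SE 0.28).

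Ccna2 was higher by 4.67 (SE 0.50), Tk1 of nucleotide supply by 4.24 (SE 0.52), Mki67 by 3.47 (SE 0.49), Asns by 4.44 (SE 0.38) and Plscr1 by 5.30 (SE 0.29). Socs3 was lower (-4.12, SE 0.38), Il6ra (-3.93, SE 0.33), Txnip (-1.92, SE 0.23), Igfbp4, which binds growth factors, (-4.44, SE 0.49) and Rab6b (-3.79, SE 0.36). In all, 2658 genes were higher and 3209 lower. All 32 cell cycle genes were up (32, and 32 over the list alone, median 2.76, adjusted p = 9.67e-17, and 0.240 with estimated correlation). Oxidative phosphorylation had 18 up and 1 down (18 and 1 over the list alone, median 0.46, adjusted p = 1.03e-06, and 0.0773 with estimated correlation). The cytotoxic list had 12 up and 1 down (12 and 1 over the list alone, median 1.06, adjusted p = 0.000478, and 0.234 with estimated correlation). Interferon response had 10 of 17 down (12 over the list alone, median -1.05, adjusted p = 0.00629, and 0.532 with estimated correlation). The count of 5867 became 1084 in a fit of all 28 arrays and 132 with the beta-actin measure as a covariate, which ended the call of the cytotoxic list (adjusted p = 0.243).

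The genes called on day 2, all with at least a 2-fold change, were then followed on day 5 to ask whether their state outlasts the stimulus, with camera p values adjusted over 12 sets. In CD4 cells the 1320 genes raised on day 2 had a median of -0.08 in transient against unstimulated cells, with quartiles of -0.59 and 0.42, 175 up and 304 down (adjusted p = 0.0636), beside a median of 0.04 over all genes. In continuous against unstimulated CD4 cells the median of these genes was 0.35, with quartiles of -0.03 and 0.95, 480 up and 65 down (adjusted p = 4.70e-19, and 0.0136 with estimated correlation). Against transient cells it was 0.57 with 663 up and 109 down (adjusted p = 3.01e-18, and 0.0136 with estimated correlation). The 89 genes lowered on day 2 had a median of 0.08 in transient CD4 cells with 8 up and 12 down (adjusted p = 0.961), where the test pointed down. In continuous against unstimulated CD4 cells their median was -0.73 with 5 up and 39 down (adjusted p = 4.18e-11, and 0.118 with estimated correlation).

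In CD8 cells the 928 raised genes had a median of 0.09 in transient against unstimulated cells, with 241 up and 133 down (adjusted p = 0.00683, and 0.440 with estimated correlation), and it turned to -0.09 with the beta-actin measure as a covariate. In continuous against unstimulated CD8 cells their median was 0.99 with 624 up and 47 down (adjusted p = 4.03e-33, and 0.00742 with estimated correlation). Against transient cells it was 0.79 with 564 up and 16 down (adjusted p = 4.52e-46, and 0.00421 with estimated correlation). The 107 lowered genes had a median of -0.03 in transient CD8 cells with 22 up and 22 down (adjusted p = 0.771). In continuous against unstimulated CD8 cells it was -1.15 with 4 up and 79 down (adjusted p = 6.84e-13, and 0.118 with estimated correlation). Against transient cells it was -1.09 with 0 up and 90 down (adjusted p = 7.27e-27, and 0.0275 with estimated correlation). The medians over all genes ranged from -0.12 to 0.04 in these comparisons.

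**Figure D4:**
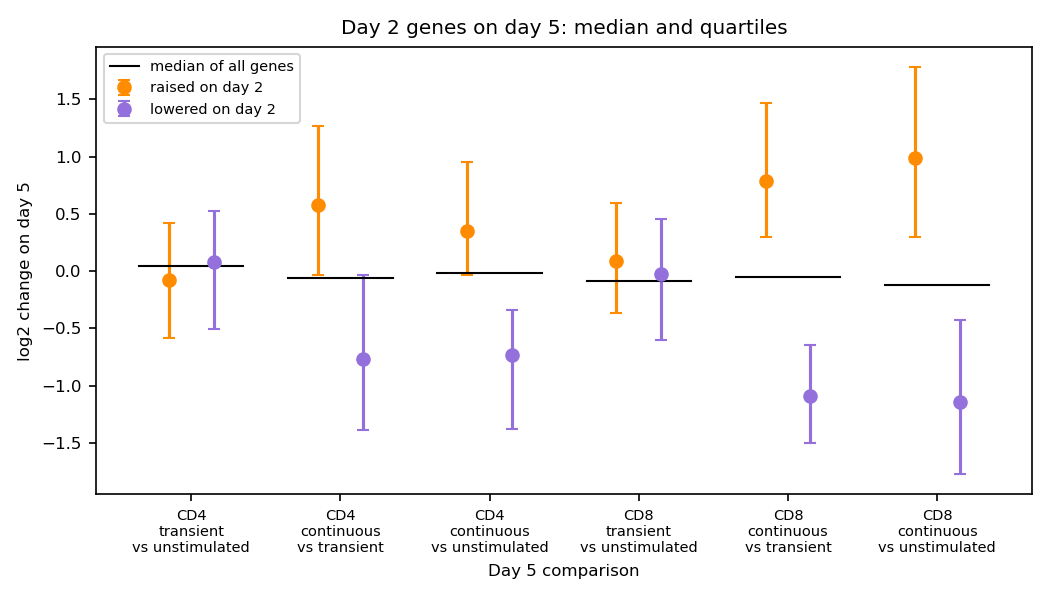
Median and quartiles of the day 5 log2 fold change of genes raised or lowered on day 2, by cell type and comparison, with a black line at the median of all genes. The raised genes have medians of -0.08 and 0.09 in transient CD4 and CD8 cells and of 0.35 and 0.99 in continuous cells, each against unstimulated cells.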

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

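The test of B cells was chosen only after its result was seen, and the test on the beta-actin slope replaced an earlier one before its own value was computed. Marker levels and the beta-actin measure of each array had been seen before both tests.

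CD4 and CD8 cells differed in their transient response on day 5, with 4642 genes called for the difference of both contrasts, and their responses ran against each other across genes (r = -0.52). They also differed in the effect of continuous against transient stimulation, with 2340 genes called. T cell genes were among both, such as Ccr9, lower in transient CD8 cells (-6.31, SE 0.64, for the difference), and Il21, higher in continuous CD4 cells (-6.13, SE 0.41). In the transient difference were also the proteasome genes Psmb7 at 7.88 (SE 0.27) and Psmc5 at 6.10 (SE 0.36).

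The beta-actin measure was high in CD4 transient and CD8 unstimulated cells, so it rose by 1.75 in the CD4 and fell by 1.40 in the CD8 transient response. Probe sets of 1 gene were called in opposite directions for 224 genes in the transient response of CD4 cells and 356 in that of CD8 cells, and for 360 and 580 in continuous against transient CD4 and continuous against unstimulated CD8 cells. In continuous against transient CD8 and continuous against unstimulated CD4 cells, where the measure did not move, these counts were 54 and 45. On day 2, where the measure moved too, they were 4 and 0 in CD4 and CD8 cells, among fewer genes with a called probe set (1873 and 1363). In the difference of continuous against transient cells, where the measure moved in CD4 cells, the count was 73, and in that of the transient responses 546. On day 5 the counts thus follow the measure within each cell type, which is consistent with, but does not show, probe sets at different distances from the 3' end reading shortened RNA or amplification product. As a test, the slope of each gene on the measure within groups was correlated across genes with the difference of the responses. The value was r = -0.15, inside the -0.30 to 0.30 of 100 permutations within groups, where the measure varied little (SD 0.194). So the test cannot part RNA quality from lineage.

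An earlier form of this test predicted that the correlation of the CD4 and CD8 responses would rise above -0.1 with the measure as a covariate if it were the cause, and stay below -0.3 if not. It came out at -0.78. That form was set aside, after the call counts with the covariate had been seen, because the slope comes from little variation and its noise enters the responses with opposite signs, since the measure moves in opposite senses. The median standard error of the CD4 response went from 0.182 to 0.538 with the covariate.

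The B cell marker list had a mean of 9.28 ± 0.64 in CD4 transient, 6.50 ± 0.75 in unstimulated and 6.09 ± 0.66 in continuous CD4 cells. It was also high on 1 unstimulated (8.96) and 1 continuous CD8 array (8.28), beside 5.95 to 7.73 on the other CD8 arrays. Sorting should remove B cells, whose RNA may account for these levels and could dilute transcripts of CD4 transient cells. Dilution lowers T cell genes alike, and the 7 pan T cell genes had a median of -0.63 (-0.92 to 0.08). Cd4, also a T cell marker, was lower by more (-1.63, SE 0.19), as were the 684 genes at least 2-fold lower (not tested). Of the 1624 lower genes 2 passed a test for a fall below the lower confidence limit of Cd4 (-2.04). They were Pdlim4 (-3.99, SE 0.29) and Psmb7 (-3.97, SE 0.21), at an adjusted p below 0.05 over all genes, which argues against dilution for these 2. For the others this limit, from the lowest marker, cannot decide, though some (Psmc5 -3.30, Phpt1 -3.25) lay below it. The beta-actin measure moved here too. The 2-fold count and the 4-fold one (69) were earlier forms, set aside once seen.

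The poly-A spike controls, which are added to RNA before amplification and enter no comparison, gave a signal on day 5 that was 6.31 log2 units above that of day 2. Their mean was 4.20 on day 2 (3.25 to 4.83) and 10.5 on day 5 (8.49 to 12.3). The arrays of both days therefore differ in preparation as well as in day, and no contrast above spans both days.

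For the other splits of the arrays, 3 against 3 arrays give 10 splits, which are too few for a share under 0.05. In each comparison below 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 1409 and 0 for CD4 cells on day 2, 1035 and 0 for CD8 cells on day 2, and 3376 and 0 for continuous against transient CD8 cells. They were 5867 and 1 for continuous against unstimulated CD8 cells. For transient against unstimulated CD8 cells, where numbers pair the arrays, they were 3937 and 0, and 4 splits part every pair.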

How the results depend on the processing

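Of the alternatives below, leaving out the third unstimulated day 2 arrays, the beta-actin and myeloid covariates and the crossed pairing were chosen only after the data were seen. Where no reason is given, the cause was not tested.

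Counts of called genes within 1.5 times of the reported ones came from all probe sets, the mean of probe sets, leaving out low values, trend and robust moderation, and the replicate block in all comparisons, and from the myeloid covariate in those of day 5. At an adjusted p below 0.01 the counts were 521 for the CD4 and 366 for the CD8 day 2 response. For transient against unstimulated cells they were 1571 in CD4 and 2470 in CD8 cells, with 3091 for the difference. For continuous against transient CD8 cells the count was 2150, for that difference between cell types 1167, and for continuous against unstimulated CD4 cells 1459. These follow from the stricter threshold, as do the counts at 2-fold or more. Those were 1112 and 1060 for the transient CD4 and CD8 response, 2856 for the difference, 1855 and 1088 for continuous against transient CD4 and CD8 cells, 1331 for the difference, and 1048 and 2096 for continuous against unstimulated CD4 and CD8 cells.

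A single fit of all 28 arrays called 3667, 3395 and 4 genes for the day 2 responses of CD4 and CD8 cells and their difference, where limma alone on day 2 called 0 for the last. On day 5 it called 87, 239 and 525 for the transient responses and their difference, 618, 360 and 22 for continuous against transient cells and their difference, and 329 and 1084 for continuous against unstimulated cells. This fit pools the larger spread of day 2 with the smaller one of day 5.

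Scaling moved the day 2 counts. Quantile normalization gave 2922 and 2609 for CD4 and CD8 cells, and median centring 5900 and 4983, with 1 gene for the difference. Array weights gave 4402, 6420 and 11, and 5135 for continuous against transient CD8 cells on day 5. A fit of the compared groups alone gave 419 for CD8 cells on day 2. Without the third unstimulated arrays of both cell types the day 2 counts were 8139, 4691 and 308.

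The beta-actin 3' minus 5' covariate left 4, 156 and 11 genes for the transient responses and their difference, 2, 2248 and 4 for continuous against transient cells and their difference, and 132 for continuous against unstimulated CD8 cells. It is nearly fixed by group in these comparisons, so that the median standard error of the transient CD4 response went from 0.182 to 0.538. It turned the sign of Cd4 in the difference of the transient responses (-0.29), of Il7r in continuous against transient CD4 cells (0.99) and of S1pr1 (-0.207) and Lef1 (-0.183) in transient CD8 cells.

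Where arrays share only a number, the replicate block gave 1891, 1550 and 0 genes for the day 2 responses of CD4 and CD8 cells and their difference. On day 5 it gave 2796 for transient CD4 cells, 4576 for the difference of the transient responses, 4141, 3375 and 2177 for continuous against transient cells and their difference, and 2630 and 5784 for continuous against unstimulated cells. In continuous against transient CD8 cells every array correlated best with its own number (r = 0.17, 0.22 and 0.02), a hint from the data, and in the day 2 responses and continuous against unstimulated CD8 cells not every array did. For transient CD4 cells, whose arrays with the same number correlated at -0.21, a block by number on the 4 arrays gave 1611 genes and a crossed block 1684, which shows no gain from either pairing.

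Leaving out 1 array at a time gave 566 to 3289 genes for CD4 cells and 387 to 1692 for CD8 cells on day 2, with 0 to 2 for the difference. Leaving out the third array with the unstimulated CD4 label gave the highest value and the first stimulated CD4 array the lowest. In CD8 cells the second unstimulated array gave 1692, and the first, the second and the third stimulated arrays gave 438, 387 and 420. The transient responses ranged from 1671 to 2126 in CD4 cells, from 3049 to 3670 in CD8 cells and from 3710 to 4592 for the difference. Continuous against transient cells ranged from 3204 to 3867 in CD4, from 2391 to 3631 in CD8 and from 1574 to 2323 for the difference. Continuous against unstimulated cells ranged from 1361 to 2275 in CD4 and from 4886 to 5643 in CD8. The lowest value for CD4 cells came without the second unstimulated array in the last comparison (1361) and without the first in the transient one (1671).

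Genes raised on day 2 had a median of 0.12 in transient CD8 cells with low values left out and of -0.0879 with the beta-actin covariate, beside 0.09. With the day 2 genes chosen without the third unstimulated arrays the medians in transient CD4 cells were -0.12 for raised and 0.10 for lowered genes. Leaving out 1 array moved the medians of raised and lowered genes in transient CD4 cells from -0.09 to -0.06 and from -0.01 to 0.22. In transient CD8 cells they moved from 0.05 to 0.15 and from -0.10 to 0.05. In continuous against unstimulated cells the ranges were 0.33 to 0.40 and -0.76 to -0.65 in CD4, and 0.94 to 1.06 and -1.26 to -0.95 in CD8. In continuous against transient cells they were 0.56 to 0.58 and -0.95 to -0.68 in CD4, and 0.72 to 0.86 and -1.22 to -0.96 in CD8.

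With an estimated correlation 95 of 264 list results lost their call, and of 169 unchanged ones only 2 had a call. Without the third unstimulated arrays 10 day 2 list results lost their call, 7 gained one and 1 turned its direction. On day 5 the beta-actin covariate ended 24 and added 5, and the myeloid covariate ended 1 and added 1. Over both days leaving out low values ended 15 and added 8, median centring ended 7 and added 1, and the replicate block ended 2 and added 4. Of 264 values of named genes 152 changed their call under at least 1 alternative, of which the beta-actin covariate changed 131 and the single fit 55.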

Other observations

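Leaving out the third arrays, the tests of myeloid genes and the comparison of continuous CD8 with continuous CD4 cells were chosen only after the data were seen.

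Continuous CD8 and continuous CD4 cells, 3 arrays each with a like beta-actin measure, were compared directly. In CD8 cells 816 genes were higher, and in CD4 cells 573. The T-box factor gene Eomes was higher in CD8 cells by 4.82 (SE 0.28, adjusted p = 2.15e-07), the chemokine gene Xcl1 by 4.91 (SE 0.37, adjusted p = 4.21e-06), and the killer cell receptor genes Klrc1, Klrd1 and Klrk1 by 3.73, 3.11 and 3.04 (SE 0.32, 0.32 and 0.17). Also higher were Shmt2 of one-carbon metabolism at 1.74 (SE 0.17) and Asns at 1.96 (SE 0.38), as was Prf1, the pore protein of granules, at 1.75 (SE 0.39). Il21 was higher in CD4 cells (-6.87, SE 0.27, adjusted p = 3.31e-09), as were Tgfb3 (-4.07, SE 0.19), Gja1 (-3.88, SE 0.23), Il10 (-3.01, SE 0.33), Socs3 (-2.62, SE 0.38), the RNA sensor gene Ifih1 (-2.07, SE 0.36) and Ctla4 (-1.58, SE 0.31, adjusted p = 0.00586). Gzmb (-0.64, adjusted p = 0.676), Ifng (-0.89, adjusted p = 0.446), Pdcd1 (0.04, adjusted p = 0.977) and Mki67 (-0.07, adjusted p = 0.967) had no call. Of the 10 splits of these 6 arrays 1, the real one, gave as many genes, with 1389 beside a highest other of 2, and 10 splits are too few for a share under 0.05.

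The third unstimulated arrays of day 2 have Cd8a and Cd8b1 values that go against their labels. A score was made from 20 genes higher in CD8 and 16 higher in CD4 cells on day 5, without Cd4, Cd8a and the other lineage markers, and read on the 6 unstimulated day 2 arrays after quantile normalization of these. Arrays labelled unstimulated CD4 scored -1.28, -1.10 and 1.48, and those labelled unstimulated CD8 1.499, 1.406 and -0.999. The third array with the CD8 label minus the third with the CD4 label gave -2.48, where the first and second arrays gave 2.64 with a spread of 0.18. Against a loss of signal on both arrays, which would bring scores to the middle, the third array with the CD4 label lay 1.35 above the midpoint of the first and second arrays. Against a mixture of CD8 cells into CD4 cells, its CD4 lineage genes lay 0.19 below (-0.19) those of the first and second CD8-labelled arrays, where CD4 cells stand 0.841 above, with a spread of 0.0245. A mixture was not tested on the third array with the CD8 label. A candidate explanation that stays open is an exchange of the labels of these 2 arrays, or of the cells before hybridization. As deposited, Cd4 (7.02) and Zbtb7b (6.88) on the third array with the CD8 label go against it, being below the other CD8 arrays, and after the normalization (8.45 and 8.30) they lie near the CD4 arrays. No biological explanation was tested, since the design gives none.

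For the difference of the day 2 responses 100 splits of the arrays by cell type within each treatment were drawn. The real count from limma is 0, which every split must reach, so the splits cannot tell whether chance made the 70 genes at an unadjusted p below 0.05. The highest other count was 1317, for a split that puts the first and the third unstimulated CD4-labelled arrays and the third unstimulated CD8-labelled one on the side of the stimulated CD4 arrays. Of these splits 81 gave no gene and 7 over 100, which points to a structure of the samples other than their labels.

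Myeloid genes varied widely between day 5 arrays of 1 group. Lyz2, a lysozyme of macrophages and granulocytes, had values from 5.30 to 10.7 in continuous CD4 cells and from 5.42 to 11.9 in unstimulated CD8 cells. Csf1r, S100a8 and Tyrobp varied with it, with S100a8 at 12.4 and 4.86 on the first and second unstimulated CD8 arrays. Within groups Lyz2 correlated with the mean of the 13 other myeloid markers at r = 0.93 and rho = 0.91 over 16 arrays (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 2e-05 for the 2 relations computed). Without the 2 arrays farthest from the median r was 0.93. This is consistent with RNA of myeloid cells carried through the sort in varying amounts, although the cells were sorted for purity. Against the beta-actin measure Lyz2 had r = -0.42 (permutation p = 0.10, adjusted p = 0.10) and rho = -0.44 (permutation p = 0.091, adjusted p = 0.091), and r = -0.62 without the 2 farthest arrays, so a share of RNA quality in it cannot be told apart. With the mean of the myeloid markers as a covariate 1 of the named genes changed its call.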
